A study of Mus musculus with 2 samples.

How the data were processed

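5-methylcytosine (m5C) in lung mRNA was measured in 2 C57BL/6 mouse libraries, 1 from control lung and 1 from lung exposed to fine particulate matter (PM2.5). Both carry a stated age of 4 weeks. The groups were taken from the stress label of each sample. Both titles also hold 12W, whose meaning is not given in the sources used here, and it was not used.

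Per the labels' protocols, purified mRNA was mixed with a small share of in vitro transcribed Dhfr mRNA, which carries no m5C and serves as the conversion control. The mixture was fragmented and treated with bisulfite, which converts unmethylated cytosine to uracil and leaves m5C as cytosine. Libraries were then made with random hexamers and a stranded kit. Per the submitters' processing notes, the reads were placed on mm10 and bedtools was used. The aligner, the site caller, the statistical filter for sites and the conversion rate are not given in the sources used here.

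The authors deposited 1 list of sites per library. Each site has a position, a strand, the count of unconverted (methylated) reads and the count of all reads, per the file headers. The deposited m5C level is a fraction from 0 to 1. The values show that every listed site had a coverage of at least 15 reads, at least 2 methylated reads and a level of at least 0.1. A cytosine missing from a list can therefore be unmethylated, below these minimums or uncovered, and its level is not known from the list. At 42 control sites and 56 PM2.5 sites the deposited level lay above the ratio of the 2 counts by more than 0.0006, and at no site did it lie below. The deposited level was used for all levels, and the counts were used for all tests and intervals.

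Identical repeated entries were removed, 67 of 4070 in the control list and 178 of 10551 in the PM2.5 list. This left 4003 control sites and 10373 PM2.5 sites. Coverage of listed sites had a median of 20 reads (quartiles 17 and 29) in both libraries, and the highest coverage was 3912 reads in the control library and 5677 in the PM2.5 library. The lists cover part of each library, so their summed coverages are not its depth.

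Sites were given genes by position alone, from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. The table holds gene bodies without strand or exons. A site took the gene whose body held it, or the 1 protein-coding gene where several bodies overlapped. This replaced the planned match on the same strand. In the control list 3763 sites (94.0%) lay in 1 protein-coding gene body and 100 (2.50%) were left without a gene because several overlapped. The PM2.5 list had 9701 (93.5%) and 309 (2.98%). Location in exon, intron or untranslated region and the sequence around each site were planned but not analysed here, because they need exons and a genome sequence. Mitochondrially encoded genes were taken by chromosome, since the gene table writes their symbols without the planned prefix.

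Each group has 1 library, so differences between the libraries have no replicate check and no p-value was computed across genes or for the conditions. Numbers of sites and genes, their overlap and their levels were compared as descriptions. Sites in both lists with a coverage of at least 20 in both libraries were tested with Fisher's exact test, two-sided, on methylated and unmethylated reads, with Benjamini-Hochberg adjustment over the sites tested and a threshold of 0.05. That test compares the 2 libraries, not the conditions. Shares of a single library are given with exact Clopper-Pearson 95% intervals, medians with order-statistic intervals and ratios of site counts with intervals from the exact binomial one. All of these cover counting error only, since reads made by PCR and neighbouring sites on the same fragment are not independent. Sites with another listed site within 10 nt on the same strand are called clustered and the others isolated.

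The test was checked on simulated reads for the 620 tested sites at their real coverages. Where a difference of 0.1 was added, 17 of 100 sites were called, and 13 of 27 among those with a coverage of at least 100 in both libraries. Where 0.3 was added, 75 of 100 were called, and 38 of 38 at that coverage. None of 420 unchanged sites was called. The simulated reads were independent, without PCR copies or fragments shared by neighbouring sites. The check therefore does not show how often real sites would be called in error.

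The 23 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The lists were m5C machinery, extracellular matrix and fibrosis, cytokines and chemokines with their receptors, NF-kB with Toll-like receptor and inflammasome signalling, and antigen presentation. Cell-type lists were T and B cells, macrophages with monocytes and dendritic cells, neutrophils, alveolar type II cells, alveolar type I cells, airway cells, endothelium, fibroblasts with smooth muscle and mesothelium, cardiac muscle and erythroid cells. The remaining lists were xenobiotic and oxidative stress response, oxidative phosphorylation, glycolysis, translation factors, chaperones, cytoskeleton, ribosomal proteins and mitochondrially encoded genes. Some genes stand in more than 1 list, such as Lyz2, Csf1r, Csf3r, Cxcl15, Pdgfra and Mmp9. For a list with at least 5 shared sites, the median difference in level was placed among 10000 random sets of shared sites drawn from the same 5 bins of coverage. The share of member genes listed in the PM2.5 library alone was placed in the same way among random gene lists, a measure chosen after the data were seen. Most lists lay below the middle of random lists by that measure, so their percentiles are best set against each other. Shared sites of 1 gene lie close together, so random sets of single sites understate the spread of a list's median.

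Named genes follow 5 parts of a rule. These are up to 10 shared sites with the largest increase and up to 10 with the largest decrease past the test's threshold, and up to 10 sites of 1 library alone with the highest coverage and a level of at least 0.2. In these, each gene gives 1 site. The rule adds the 5 genes with the most sites in each library, up to 4 member sites of highest coverage per gene list, and up to 10 sites in mitochondrial and m5C machinery genes. Other members are named from their numbers of sites, after those were seen. Neighbouring sites can be carried by the same reads, so the number of sites in a gene is not a number of independent observations.

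The alternatives tried were coverage minimums of 30, 50 and 100, level minimums of 0.2 and 0.3, removal of clustered sites, windows of 5 and 20 nt, overlap within 5 nt or without strand, means or pooled reads, a minimum difference of 0.1 and a chi-square test. Alternatives added after the data were seen were the removal of mitochondrial sites or of sites with a level of at least 0.9, each strand alone, repeated entries kept, sites in exactly 1 gene body, 1 value per gene, and levels or counts taken from the other deposited column. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.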

Results

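Transcriptome-wide m5C was profiled in mouse lung mRNA by RNA bisulfite sequencing, with 1 library from control lung and 1 from lung after exposure to PM2.5, airborne particles small enough to reach the alveoli. The comparison asks how the m5C profile of lung mRNA differs after PM2.5 exposure. The control list held 4003 sites whose coverages added up to 204446, and the PM2.5 list held 10373 sites whose coverages added up to 380571. A read that spans several sites counts at each of them in these sums. There was no replicate in either group, so every difference given here is between 2 libraries.

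The PM2.5 library had 2.59 times as many listed m5C sites as the control library, and its sites lay in 2741 genes against 1443, a ratio of 1.90. The gene with the most control sites was Scgb1a1, the secretoglobin of airway club cells, with 75 sites on chromosome 19 between positions 9083642 and 9087944 (mm10). All 75 were also listed in the PM2.5 library, with a median level of 0.258 in the control and 0.243 in the PM2.5 library at median coverages of 782 and 806 reads. Myo3a, a class III myosin, followed with 61 control and 60 PM2.5 sites, and the mitochondrial genes ND4, COX3 and ND5 came next in the control library with 59, 55 and 55 sites. Tenm2, a teneurin, also had 55 control sites, at a lower coverage, and no PM2.5 site. In the PM2.5 library these 3 mitochondrial genes had 78, 83 and 65 sites.

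The 2 genes with the most PM2.5 sites had none in the control library. Zfp566, a zinc-finger gene, held 89 PM2.5 sites between positions 30079697 and 30079836 of chromosome 7, with a median level of 0.514 at a median coverage of 36 reads. Crebbp, the histone acetyltransferase CBP, held 88 between positions 4106095 and 4172141 of chromosome 16, with a median level of 0.411 at 34 reads. All sites of both genes were clustered, so the same fragments could carry many of them. Blocks of unconverted or misplaced reads were not tested as their source. The difference in number depended on coverage. At 15 to 19 reads the libraries had 1953 control and 4414 PM2.5 sites, a ratio of 2.26 (95% interval 2.14 to 2.38). The ratio was 3.20 at 20 to 29 reads, 3.62 at 30 to 49, 1.51 at 50 to 99 and 1.33 (1.13 to 1.58) at 100 reads or more, where the lists had 245 and 327 sites. Among sites with at least 100 reads the ratio of genes was 1. Sites with only 2 or 3 methylated reads made up 60.7% of the control list and 55.8% of the PM2.5 list.

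**Figure D1:**
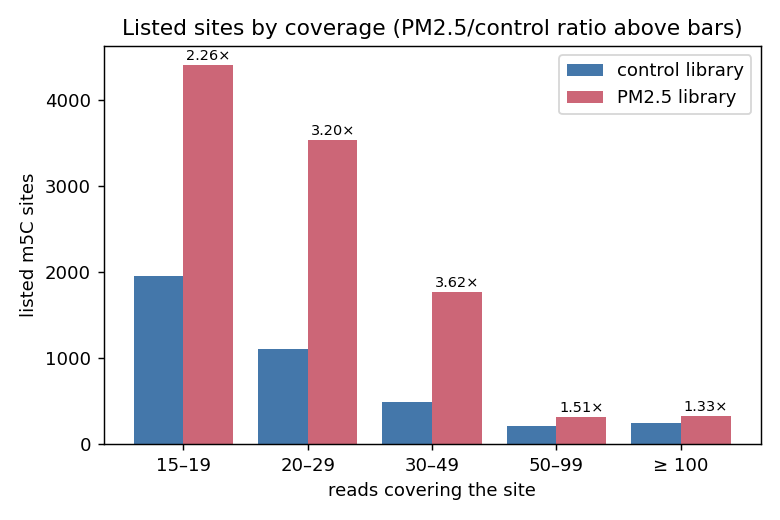
Number of listed m5C sites (vertical axis) by the number of reads covering the site (horizontal axis) in the control library (blue) and the PM2.5 library (red), with the PM2.5 over control ratio above each pair of bars. The ratio was 3.62 at 30 to 49 reads and 1.33 at 100 reads or more.

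Most listed sites were found in 1 library alone when all coverages were taken. The lists shared 886 sites, which were 22.1% of the control sites (exact 95% interval 20.9 to 23.5%) and 8.54% of the PM2.5 sites (8.01 to 9.10%), leaving 3117 control-only and 9487 PM2.5-only sites. The shared percent of control sites was 47.8 at a coverage of at least 30, 69.5 at 50 and 67.3 at 100, and 52.3 at a level of at least 0.2. At the level of genes, 616 had a site in both libraries, 827 in the control alone and 2125 in the PM2.5 library alone. The shared sites lay in 138 genes. Their median coverage was 35 reads in each library, and the median over genes of the PM2.5 over control coverage ratio was 0.880 (bootstrap 95% interval 0.791 to 0.986).

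Among well-covered sites listed in the control library alone, Gne, the bifunctional enzyme of sialic acid synthesis, had a site at position 44081091 of chromosome 4 with 264 of 264 reads methylated. Gne also held a PM2.5-only site, at position 44081103, with 54 of 62 reads (87.1%, exact interval 76.1 to 94.3%). Nid2, which encodes nidogen-2, had a control-only site at position 19752452 of chromosome 14 with 29 of 74 reads (39.2%, 28.0 to 51.2%), and Col4a2, a collagen IV chain, had one at position 11400946 of chromosome 8 with 21 of 51 reads (41.2%, 27.6 to 55.8%). Both genes also had other sites in the PM2.5 library. Ntn1, which encodes the guidance molecule netrin-1, had 21 of 44 reads at position 68212866 of chromosome 11. Atxn10 had 36 of 39 reads at position 85443524 and Cpne8 had 35 of 35 reads at position 90653098, both on chromosome 15. The Gne, Atxn10 and Cpne8 sites were clustered. These genes held 10, 17 and 9 control sites with a level of at least 0.9, and runs of such sites are weighed in the last part. The mitochondrial gene ND5 had 11 of 50 reads at position 12810, Glcci1 had 9 of 43 at position 8509600 of chromosome 6, and Ppp1r9b had 6 of 30 at position 94992238 of chromosome 11. Epas1, the hypoxia-inducible factor HIF-2 alpha of endothelium, was listed at position 86830946 of chromosome 17 with a deposited level of 0.333, while its counts were 5 of 211 reads (2.37%, 0.774 to 5.44%).

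Among PM2.5-only sites with a level of at least 0.2, the one of highest coverage was in Lars2, the mitochondrial leucyl-tRNA synthetase, at position 123462032 of chromosome 9 with 126 of 614 reads (20.5%, 17.4 to 23.9%). Kcnh7, a voltage-gated potassium channel, had 125 of 125 methylated reads at position 62947239 of chromosome 2. That site was clustered, and Kcnh7 held 28 PM2.5 sites with a level of at least 0.9. Ctnnb1, which encodes beta-catenin, had 12 of 58 reads (20.7%, 11.2 to 33.4%) at position 120959931 of chromosome 9. Mgp, an inhibitor of calcification, had 13 of 57 at position 136875712 of chromosome 6, and Oaz1, the ornithine decarboxylase antizyme, had 12 of 45 (26.7%, 14.6 to 41.9%) at position 80829033 of chromosome 10. Setd6 had 12 of 54 reads at position 95716423 of chromosome 8, Sec14l3 had 12 of 53 at position 4075438 of chromosome 11, and Tedc2 had 10 of 49 at position 24217916 of chromosome 17. Grik3, a kainate receptor subunit, had 6 of 59 reads (10.2%) at position 125504594 of chromosome 4, where the deposited level was 0.273. A site listed in 1 library alone has no measured level in the other.

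Listed sites had a median level of 0.133 in both libraries (95% intervals 0.13 to 0.133 in the control and 0.133 to 0.136 in the PM2.5 library). The quartiles were 0.111 and 0.19 in the control library and 0.115 and 0.2 in the PM2.5 library. Sites below 0.2 made up 75.5% of the control list and 74.8% of the PM2.5 list. Sites with a level of at least 0.9 made up 6.42% of the control list (5.68 to 7.22%) and 3.39% of the PM2.5 list (3.05 to 3.76%). These medians are of listed sites, all of which lie at 0.1 or above. They moved apart with coverage, to 0.158 in the control and 0.133 in the PM2.5 library at a coverage of at least 30 and 0.194 and 0.16 at 50, and lay at 0.19 and 0.195 at 100.

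At the 886 shared sites the median difference in level, PM2.5 minus control, was 0 (95% interval 0 to 0.005). The level was higher in the PM2.5 library at 435 shared sites, lower at 320 and equal at 131, and the difference was under 0.1 at 709 of them (80.0%). Across the shared sites Pearson's r was 0.964 and Spearman's rho 0.855, where neighbouring sites are not independent replicates. Of 620 shared sites tested, 11 passed the threshold of Fisher's exact test after Benjamini-Hochberg adjustment, 8 with a higher level in the PM2.5 library and 3 with a lower one. Without adjustment 65 had a p under 0.05.

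Gphn, which encodes the synaptic scaffold gephyrin, held 6 of the 8 sites that were higher in the PM2.5 library. All 6 lay between positions 78351140 and 78351164 of chromosome 12, close enough for the same fragments to carry several of them. The largest increase was at position 78351164, from 34 of 126 reads (27.0%, 19.5 to 35.6%) to 78 of 160 (48.8%, 40.8 to 56.8%; Fisher's exact test, adjusted p = 0.0134). Lars2 was higher at position 123462026 of chromosome 9, with 58 of 565 reads (10.3%) in the control and 122 of 586 (20.8%) in the PM2.5 library (Fisher's exact test, adjusted p = 0.000191). Near these sites, control and PM2.5 levels were 0.836 and 0.881 at Gphn position 78351155 and 0.873 and 0.894 at Lars2 position 123462017. Genes were given by position without exons, so whether these reads came from Gphn or Lars2 mRNA was not tested. Igfbp6, a binding protein of insulin-like growth factors, had the deepest site of both lists, at position 102149253 of chromosome 15. Its share of methylated reads was 33.2% (31.7 to 34.7%) of 3912 reads in the control and 39.0% (37.7 to 40.3%) of 5677 in the PM2.5 library (Fisher's exact test, adjusted p = 3.55e-06).

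Thbs3, a thrombospondin of the extracellular matrix, showed the largest decrease, at position 89217880 of chromosome 3, from 97 of 169 reads (57.4%, 49.6 to 65.0%) in the control to 17 of 71 (23.9%, 14.6 to 35.5%) in the PM2.5 library (Fisher's exact test, adjusted p = 0.000277). Selenop, the plasma selenium carrier, was lower at adjacent positions 3274736 and 3274737 of chromosome 15, with levels of 0.235 and 0.227 in the control and 0.183 and 0.177 in the PM2.5 library (Fisher's exact test, adjusted p = 0.00523 for each). The Thbs3 and Igfbp6 sites were isolated, while those of Gphn, Lars2 and Selenop were clustered. At the coverage of most shared sites only large differences could be detected, since simulated differences of 0.1 were called at 17 of 100 sites.

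**Figure D2:**
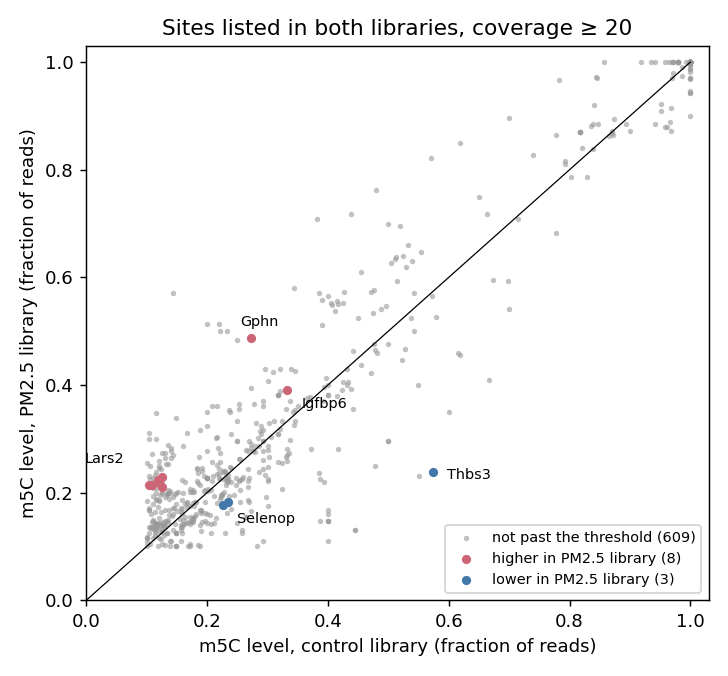
m5C level in the PM2.5 library (vertical axis, fraction of reads) against the control library (horizontal axis, fraction of reads) for the 620 shared sites tested, each point 1 site, with the line of equal levels. The 8 sites higher in the PM2.5 library are red, the 3 lower ones blue, and the others grey.

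Neighbouring sites were common in both libraries. Clustered sites made up 63.4% of the control list (61.9 to 64.9%) and 67.9% of the PM2.5 list (67.0 to 68.8%). The order turned with coverage, with 74.9% of control and 70.2% of PM2.5 sites clustered at a coverage of at least 30 and 83.0% and 76.4% at 50. Their median level was 0.136 in the control and 0.143 in the PM2.5 library, against 0.125 at isolated sites of each. Of the shared sites, 799 were clustered in both libraries and 53 were isolated in both. The isolated shared sites had a median difference of 0.027 (95% interval -0.002 to 0.05), with 31 higher in the PM2.5 library and 19 lower. Scgb1a1 and Zfp566 sites were all clustered.

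Sites were also unevenly spread over the strands of the genome. The plus strand held 56.1% of control sites and 66.6% of PM2.5 sites. Counted once per gene, over protein-coding genes with a site in no other gene body, 917 control genes were on the plus strand and 477 on the minus strand (65.8% plus, 63.2 to 68.3%), against 1960 and 678 in the PM2.5 library (74.3%, 72.6 to 76.0%). Shared sites were split evenly, with 444 plus and 442 minus, the 75 Scgb1a1 sites among the minus ones. Of genes with a shared site, 89 of 134 were plus (66.4%, 57.8 to 74.3%). Over all genes counted by strand, the PM2.5 over control ratio was 2.14 on the plus strand and 1.42 on the minus strand.

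**Figure D3:**
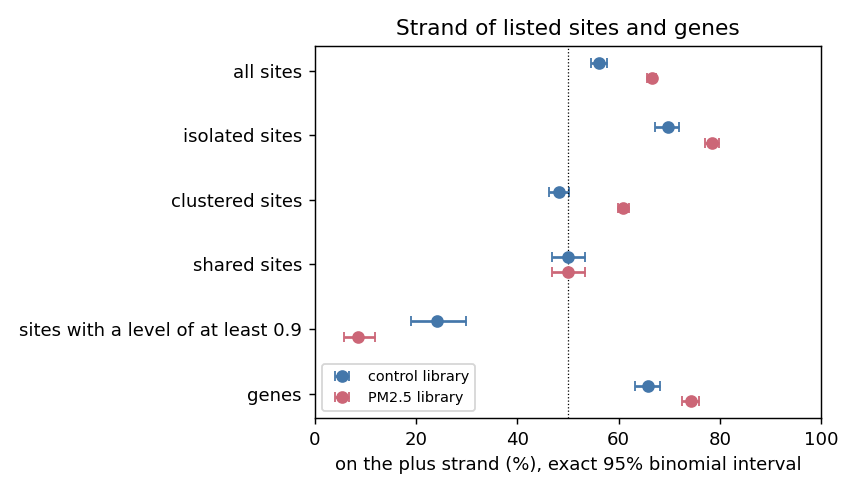
Share of sites or genes on the plus strand of the genome (horizontal axis, percent) in the control library (blue) and the PM2.5 library (red), with exact 95% binomial intervals and a dotted line at an even split. Genes were 65.8% plus in the control and 74.3% in the PM2.5 library.

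Epithelial genes had sites in both libraries more often than not. Of alveolar type II genes, 10 had a control site and all 10 also had a PM2.5 site, and 4 more had PM2.5 sites alone. Sftpc, the surfactant protein C gene, had 4 shared sites, the deepest at position 70522193 of chromosome 14 with a level of 0.215 at 389 reads in the control and 0.301 at 360 reads in the PM2.5 library. Scd1, a fatty acid desaturase, had 23 control sites and 1 PM2.5 site, and Cxcl15, a lung chemokine, had 1 and 22. At the 37 shared sites of the list the median difference was 0.015, at percentile 90.1 of random sets. Of these sites, 29 lay in Lyz2, which also stands in the macrophage list. Of alveolar type I genes 9 had sites in both libraries and 3 in the PM2.5 library alone. Ager, the receptor for advanced glycation end products, had levels of 0.252 at 103 reads and 0.365 at 64 reads at position 34600347 of chromosome 17. Of the 4 shared sites of the list, all in Ager, 1 was higher in the PM2.5 library and 3 were lower. Airway genes were listed for 6 in the control and 7 in the PM2.5 library, 6 of them shared, with Cyp2b10, a cytochrome P450, found with 15 PM2.5 sites alone. The median difference over 86 shared airway sites, 75 of them in Scgb1a1, was 0 (percentile 2.92).

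Immune genes numbered more in the PM2.5 than in the control library, as genes overall did. Of cytokine, chemokine and receptor genes, 4 had control sites and 12 had PM2.5 sites, including all 4. Csf3r, the receptor of granulocyte colony-stimulating factor, had 30 PM2.5 sites and Il10rb, a subunit of the interleukin 10 receptor, had 19, with no control site in either. Such neighbouring sites can come from the same few reads. The adjacent Csf3r positions 126028161 and 126028162 of chromosome 4 both had a PM2.5 level of 0.108 at 37 reads. Antigen presentation had 3 control and 12 PM2.5 genes, of which 10 were listed in the PM2.5 library alone, among them Tapbp with 7 sites, Ciita with 5 and Tap2 with 4. The class II gene H2-Ab1 had levels of 0.103 at 29 reads and 0.3 at 30 reads at position 34263338 of chromosome 17, and the class I gene H2-D1 had 0.15 at 61 reads and 0.165 at 98. Macrophage, monocyte and dendritic cell genes numbered 5 in the control and 10 in the PM2.5 library, with Chil3, a chitinase-like protein of macrophages, at 41 PM2.5 sites and no control site. Lyz2, the lysozyme gene, had 32 control and 48 PM2.5 sites, and Csf1r, the receptor of macrophage colony-stimulating factor, had 0.298 at 285 reads and 0.191 at 251 at position 61129085 of chromosome 18. The 30 shared sites of this list, 29 of them in Lyz2, had a median difference of 0.0055 (percentile 74.4). Neutrophil genes had no control site and 4 PM2.5 genes, which were Csf3r, Ltf, Mmp9 and Lcn2. T and B cell genes had no control site and 3 PM2.5 genes, Cd8a with 2 sites and Prf1 and Cd37 with 1 each. NF-kB and Toll-like receptor genes numbered 5 and 6, with Rela at 0.163 (565 reads) in the control and 0.155 (296 reads) in the PM2.5 library. The share of genes listed in the PM2.5 library alone was 76.9% for antigen presentation (percentile 91.3 of random lists), 66.7% for cytokines (percentile 69.9), 58.3% for macrophages (percentile 48.4) and 37.5% for NF-kB signalling (percentile 12.01). Among sites with a coverage of at least 50, cytokine genes numbered 2 in the control and 1 in the PM2.5 library, antigen presentation genes 2 and 2, macrophage, monocyte and dendritic cell genes 2 and 5, NF-kB signalling genes 1 and 1, and neutrophil, T and B cell genes none in either. On the plus strand, cytokine genes numbered 4 in the control and 11 in the PM2.5 library and antigen presentation genes 3 and 11. On the minus strand both lists had 0 control genes and 1 PM2.5 gene. Macrophage, monocyte and dendritic cell genes numbered 3 and 7 on the plus strand and 2 and 3 on the minus strand. For NF-kB signalling these numbers were 3 and 4, and 2 and 2. The random lists were matched on coverage but not on strand.

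Extracellular matrix and fibrosis genes were listed for 25 in the control and 23 in the PM2.5 library, 13 in both. The direction turned with coverage, with 5 control and 10 PM2.5 genes at a coverage of at least 30 and 4 and 1 at 50. The share listed in the PM2.5 library alone was 28.6%, at percentile 0.065 of random lists. Lama3, a laminin chain, had 10 control sites and 1 PM2.5 site, and the integrin Itga8 had 9 control sites alone. The platelet-derived growth factor receptor Pdgfra had 2 control and 25 PM2.5 sites, Pdgfrb had 10 PM2.5 sites alone, and Tgfb1, the transforming growth factor gene, had 1 and 12. Sparc, a matricellular protein gene, had 4 of the 5 shared sites of the list, with a level of 0.111 at 45 reads and 0.158 at 19 at position 55394638 of chromosome 11. The 5 shared sites had a median difference of 0.005 (percentile 65.2). Endothelial genes numbered 13 and 16, with 10 in both (31.6% in the PM2.5 library alone, percentile 1.36). Epas1 had 10 control and 29 PM2.5 sites and none shared, and Vwf, the von Willebrand factor gene, had a PM2.5-only level of 0.105 at 239 reads. Fibroblast, smooth muscle and mesothelial genes numbered 7 and 8, 3 of them in both, and Gsn, the gelsolin gene, had 0.23 at 61 reads and 0.125 at 64 at position 35307581 of chromosome 2. Of the 3 shared sites of that list, all in Gsn, 2 were higher in the PM2.5 library and 1 was lower. Of cardiac muscle genes 2 were listed in the control and 5 in the PM2.5 library, with Myl4 at 0.114 (376 reads) and 0.164 (415 reads) and Actc1 at 10 PM2.5 sites alone. The erythroid list had Hbb-bs and Hbb-bt in both libraries. All 16 Hbb-bs sites were shared, and the 17 shared sites of the list had a median difference of 0.01 (percentile 65.8).

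Xenobiotic and oxidative stress genes numbered 11 in the control and 14 in the PM2.5 library, 6 in both, but 6 and 3 on the minus strand. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, had 24 control sites and no PM2.5 site, and Gstp1, a glutathione transferase, had 8 and 1. Cyp1a1, an aryl hydrocarbon receptor target, had 1 PM2.5 site alone. The 8 shared sites of the list, 5 of them in Gstm1, had a median difference of -0.047 (percentile 1.52), and Gstm1 had 0.138 at 29 reads and 0.1 at 20 reads at position 108012432 of chromosome 3. Translation factor genes were listed for 12 in the control and 11 in the PM2.5 library, 7 in both, and for 3 and 5 at a coverage of at least 30 and none and 3 at 50. Eif3c and Pabpc1, the poly(A) binding protein gene, had 21 and 20 control sites and 1 PM2.5 site each, whereas Eif4g2 had 3 control and 20 PM2.5 sites. Eef1a1, an elongation factor, had 3 and 20. Ribosomal protein symbols numbered 19 and 27, 11 in both, with 11 shared sites at a median difference of 0.028 (percentile 89.5). Rpl13a had 0.257 at 35 reads and 0.125 at 48 at position 45127046 of chromosome 7. Nearby, its level was higher in the PM2.5 library at position 45127050 (0.125 and 0.273) and at position 45127051 (0.143 and 0.571, at 21 reads each). None of these differences passed the threshold of Fisher's exact test. The symbol pattern also took in Rps6ka1, a kinase.

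Cytoskeleton and focal adhesion genes numbered 13 in the control and 22 in the PM2.5 library, 11 in both. Actg1, a cytoplasmic actin, had 32 sites, the non-muscle myosin Myh9 had 26 and the filamin Flna had 17, all in the PM2.5 library alone, while profilin Pfn1 had 10 control sites alone. The 6 shared sites of the list had a median difference of -0.008 (percentile 22.9). Chaperone genes numbered 5 and 6, 2 in both, but 4 and 3 without clustered sites and 3 and 1 on the minus strand, with Dnajb1 at 15 PM2.5 sites and Hsp90b1 at 9 control sites, each in 1 library alone. Nuclear genes of oxidative phosphorylation numbered 2 and 4, none in both, but 2 and none on the plus strand, with Ndufa10 at a PM2.5-only level of 0.165 (79 reads). Glycolysis genes numbered 2 and 2, none in both, with Slc2a1, the glucose transporter GLUT1 gene, at a control-only level of 0.1 (30 reads).

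All 12 mitochondrially encoded genes with a site were listed in both libraries, with 286 control and 431 PM2.5 sites. COX1 had 6 control and 26 PM2.5 sites, ATP6 had 3 and 23, COX2 had 4 and 23, and ND4L had 9 and 1. At the 214 shared sites the median difference was 0.021, at percentile 99.99 of random sets, with 134 higher in the PM2.5 library and 78 lower. These sites lay in 10 genes, so random sets of single sites understate the spread of this median. None of them passed the threshold of Fisher's exact test. In ND4 the median difference over 42 shared sites was 0.0585, and in ND5 it was -0.019 over 41. CYTB had a level of 0.385 at 252 reads in the control and 0.236 at 174 reads in the PM2.5 library at position 14920. Over its 19 shared sites the median difference was 0.025. ND6, on the minus strand, had 0.216 at 194 reads and 0.252 at 202 at position 13859.

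Of the m5C machinery, 3 genes were listed in each library and 1 in both. Ybx3, a cold-shock domain protein of the family that holds the m5C reader Ybx1, had 86 of 838 reads (10.3%, 8.29 to 12.5%) in the control and 52 of 305 (17.0%, 13.0 to 21.7%) in the PM2.5 library at position 131388170 of chromosome 6. The difference did not pass the threshold (Fisher's exact test, adjusted p = 0.108). Ybx1 had 3 PM2.5 sites alone, the deepest with 3 of 23 reads, and the methyltransferase genes Nsun5 and Nsun7 had 2 control and 1 PM2.5 site. Srsf2 had 1 control site with 3 of 20 reads. None of the 11 sites past the threshold lay in a gene of the 23 lists.

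**Figure D4:**
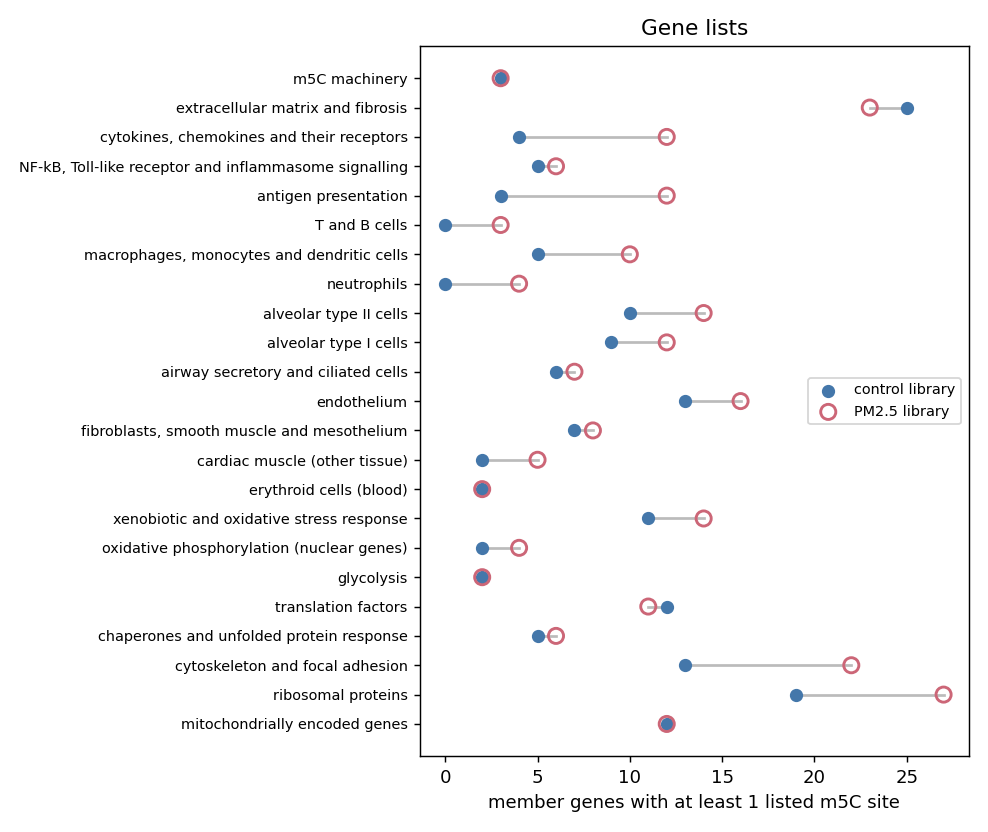
Number of member genes with at least 1 listed m5C site (horizontal axis) in the control library (filled blue) and the PM2.5 library (open red) for each of the 23 gene lists (vertical axis). Antigen presentation had 3 control and 12 PM2.5 genes, while extracellular matrix and fibrosis had 25 and 23.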

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

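The tests in this part were chosen after the result was seen. Dhfr, the gene whose in vitro transcribed mRNA was added as the conversion control, had no listed site in the control library and 2 adjacent sites in the PM2.5 library, on chromosome 13. At position 92368262 the level was 0.116, with 26 of 225 reads unconverted (exact 95% interval 7.69 to 16.5%), and at position 92368263 it was 0.112, with 25 of 224 reads. These sites stand out because they are a signal in the gene of a control transcript that the comparisons did not use. The lists do not separate reads of the lung's own Dhfr mRNA from those of the added one.

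The first pattern weighed was the larger number of PM2.5 sites. A greater depth of the PM2.5 library is argued against by the median coverage ratio at shared sites, 0.880 over 138 genes and 1.07 over sites, since it would need a ratio well above 1, although shared sites are 8.54% of the PM2.5 list and had to pass the minimum of 15 reads in both libraries. Scattered unconverted reads at weakly covered cytosines remain open, since the ratio of sites was 2.74 (2.64 to 2.85) at 15 to 49 reads and 1.33 (1.13 to 1.58) at 100 reads or more, but it was lower at isolated (2.27) than at clustered sites (2.78) and higher at 30 to 49 reads (3.62) than at 15 to 19 (2.26), and sites with 2 methylated reads made up 27.7% of the PM2.5 list and 39.6% of the control list. Poorer bisulfite conversion in the PM2.5 library remains open, since Dhfr had 2 listed sites in that library alone, at 0.116 and 0.112. Levels at shared sites were not higher throughout (median difference 0, with 435 higher, 320 lower and 131 equal, and 0.0138 with 1 value per gene). These levels cannot decide, since a small loss of conversion would move them little. At 181 shared sites the level was at least 0.9 in both libraries, which leaves little room for a rise. The conversion rates are not given in the sources used here. Blocks of unconverted or misplaced reads, such as could give the stretch of sites in Zfp566, were not tested as a source of the larger number. PM2.5 exposure also remains open and cannot be told apart from the library with 1 library per group, although the PM2.5 over control ratio of genes on the plus strand was 1.51 times that on the minus strand (bootstrap 95% interval 1.33 to 1.69).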

How the results depend on the processing

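Of 92 alternatives over 11 results, 34 stayed within the interval or range of the reported value and 58 moved; the settings for each strand, mitochondrial sites, sites with a level of at least 0.9 and 1 value per gene were chosen after the data were seen. The order of the libraries turned for the clustered percent at coverages of 30 and 50, given here with the other moved values. Unless stated, the cause was not tested, and stricter coverage also leaves fewer sites by construction. The ratio of sites was 1.42 at a coverage of at least 50, 1.33 at 100, 2.09 at a level of at least 0.3, 2.27 without clustered sites, 3.08 on the plus strand and 1.97 on the minus strand. The ratio of genes was 2.86 at a coverage of 30 and 1 at 100, 3.10 and 2.11 at levels of 0.2 and 0.3, and 2.13 and 1.44 on the plus and minus strands over all genes with a site. The shared percent of control sites was 47.8, 69.5 and 67.3 at coverages of 30, 50 and 100, 52.3 at a level of 0.2, 24.4 with sites within 5 nt counted, 18.1 without mitochondrial sites, 18.2 without sites of 0.9 or more, and 19.8 and 25.1 on the plus and minus strands. The median level of control sites was 0.158, 0.194 and 0.19 at coverages of 30, 50 and 100, 0.125 without clustered sites and also without sites of 0.9 or more, and 0.253 from pooled reads. That of PM2.5 sites was 0.16 and 0.195 at 50 and 100, 0.125 without clustered sites and 0.218 from pooled reads. The difference at shared sites was 0.007, 0.009 and 0.008 at coverages of 30, 50 and 100, 0.0125 as a mean, 0.027 without clustered sites, 0.0138 with 1 value per gene and 0.0085 on the plus strand. Clustered percents in the control and PM2.5 lists were 55.9 and 56.6 within 5 nt, 65.5 and 72.6 within 20 nt, 74.9 and 70.2 at a coverage of 30, 83.0 and 76.4 at 50, 60.9 and 66.7 without mitochondrial sites, 54.6 and 62.2 on the plus strand, and 74.7 and 79.3 on the minus strand. Sites called higher fell from 8 to 5 with a minimum difference of 0.1 and to 3 without clustered sites. They rose to 12 at a coverage of 100, within the range of the reported value. Sites called lower went from 3 to 5 and 6 at coverages of 50 and 100 and to 1 with that minimum difference. All 11 called sites were kept at coverages of 30 and 50 and with a chi-square test, and 10 of them at 100, where 18 sites were called. Without clustered sites 43 were tested and 6 called, 2 of them among the 11. Gene lists with more PM2.5 than control genes went from 17 of 23 to 10 at a coverage of at least 50. They numbered 16 on the plus strand and 12 on the minus strand, within the range of the reported value. Simulated differences of 0.1 were called at 17 of 100 tested sites, and at 13 of 27 with 100 reads or more. Location in transcripts and sequence context were not run, as they need exons and a genome sequence. No paired analysis was possible because each group has 1 library.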

Other observations

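The tests in this part were chosen after the result was seen, except the comparison of plus-strand shares between genes with and without a shared site. Several genes outside the lists, named after their values were seen, had many sites in the PM2.5 library alone. Slc8a1, the cardiac sodium-calcium exchanger gene, had 70 with a median level of 0.415, Fzr1, an activator of the anaphase-promoting complex, had 60 at 0.2, and Hlcs, which attaches biotin to carboxylases, had 54 at 0.444. Samhd1, a dNTP hydrolase, had 28 at 0.106, Tsc2, a negative regulator of mTORC1, had 26 at 0.125, and Ogt, the O-GlcNAc transferase, had 21 at 0.138. In the control library alone, Tenm2, a teneurin, had 55 sites at a median level of 0.389, Jtb had 32 at 0.133, and Nr1h3, the oxysterol receptor LXR alpha, had 17 at 0.125. Neighbouring sites can share reads, so these numbers may rest on few fragments.

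The second pattern weighed was the excess of plus-strand genes, which was seen on all 19 autosomes in both libraries. PM2.5 exposure is argued against as its whole source, because 65.8% of control genes were already on the plus strand (63.2 to 68.3%). Strand-dependent mapping or calling of weak sites stays open: genes without a shared site were 65.7% plus in the control (63.0 to 68.3%) and 74.7% in the PM2.5 library (73.0 to 76.4%), and the interval of genes with one, 66.4% (57.8 to 74.3%), was too wide for the planned comparison to exclude it. Among sites, isolated ones were more often plus than clustered ones (69.7% and 48.2% in the control, 78.5% and 61.0% in the PM2.5 library), and so were sites under 0.2 than sites of 0.9 or more (59.4% and 24.1%, 71.7% and 8.52%). A strand-dependent step that acts on all sites was not tested.

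The third pattern weighed was runs of neighbouring sites with levels of 0.9 or more. A block on chromosome 2 that ended at position 98667228, outside any gene body, held 33 control and 55 PM2.5 sites with a median level of 1, and other runs lay in Pkd2l2, Eya4 and Dpp9 in both libraries. Blocks of unconverted or misplaced reads were not tested apart from other sources of such runs, since the 98.1% of control sites at 0.9 or more with a listed neighbour within 10 nt (95.5 to 99.4%), against 61.1% of those below 0.9, describes the runs themselves. PM2.5 exposure is argued against as their whole source, because 70.4% of the control sites at 0.9 or more (64.4 to 75.9%) were at 0.9 or more in both libraries. That share starts from control sites, so it does not cover runs of the PM2.5 library alone. Of the 352 PM2.5 sites at 0.9 or more, 194 (55.1%, 49.8 to 60.4%) were also in the control list at any level. By that measure 191 of the 257 control sites at 0.9 or more (74.3%, 68.5 to 79.5%) were in the PM2.5 list. Runs at this level included Kcnh7 (28 sites) and Klra9 (25) in the PM2.5 library alone and Atxn10 (17) in the control library alone. Stretches of clustered sites at lower levels, such as that in Zfp566, were not weighed here.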
